A study of Mus musculus with 2 samples.

How the data were processed

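The data are 2 single-cell expression libraries of mCherry-sorted cells from pooled mouse tumours, 1 from young mice (4 weeks) and 1 from adult mice (24 weeks), prepared with the 10x Genomics 3' v2 kit per the labels' protocols. The deposited files hold raw UMI counts per gene and barcode, not normalised, as whole numbers in sparse matrices of 31054 features, with the genes and barcodes listed beside them. The submitters' processing notes name Cell Ranger 3.0.2 and the genome build mm10. The gene annotation and the barcode filter used for counting are not given in the sources used here, and every barcode in the files held at least 500 UMIs. The features include the mCherry construct. Of the feature identifiers, 99.6% were found in GENCODE M21, which is on the same build, and the positions of all 507 named and listed genes were taken from it. Symbols shared by more than 1 identifier (71 features) were kept apart by identifier. Reads of genes with near-identical copies, such as Hspa1a and Hspa1b, Ifit3 and Ifit3b, Stfa2, the Hist1 genes and the H2 genes, may have been split or dropped by the counting, so their counts are uncertain.

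Each library was taken to its age by the sample title. Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, which removed 468 young and 505 adult barcodes. Scrublet (in scanpy 1.11.5, expected rate 6%, run on each library) called 1 doublet per library, which was left out. That is too few for libraries of this size, so the caller has not worked and doublets should be taken as present. Leaving out the 6% of cells with the highest scores (425 young and 346 adult cells) was added as an alternative. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without mCherry, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (seed 0, no integration of the libraries) gave 18 clusters. A cluster was named after the marker list, of 20 lists fixed before the data were examined, with the highest mean share of cells with a UMI. It stayed unnamed with fewer than 3 detected markers, with more markers of another class among its 10 leading genes, or with a median UMI count under 1/3 of its libraries' and no own marker among those genes. Macrophage-like and monocyte-like clusters were joined in a single class. Clusters with a median of at least 5 mCherry UMIs were called mCherry-rich. That rule was set after the data were seen, and these cells were given no cell type. Pigment synthesis and neural crest lists had too few measured members to be used (1 of 12 pigment genes in each class).

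For each class with at least 50 cells per library, UMIs were summed per library and expressed as counts per 1000000 of the sum (CPM). The log2 ratio of young over adult used a pseudocount of 5 CPM. CPM intervals are exact Poisson, ratio intervals are conditional binomial (Clopper-Pearson), share intervals are exact binomial (Clopper-Pearson) and intervals of share ratios use the log scale, all at 95%. A count of 0 was read as allowing up to 3 counts. Cells are not replicates, so no p-value or standard error was computed. Genes named in the text were chosen by a rule fixed before the data were examined. Among genes at 50 CPM or more in at least 1 library, without mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, the rule took the 10 largest log2 ratios in each direction in monocyte/macrophage-like and mCherry-rich cells and the 5 largest in each direction in neutrophil-like and T cell-like cells. To these it added the leading 2 to 4 members of each described list and all sex-linked genes. Others are said to have been chosen later or stand beside a list as further members. The 32 gene lists were fixed at the same time. A member was measured at 10 CPM or more in at least 1 library and counted as higher or lower at 1.5-fold with an interval that excluded 1. A list of at least 4 measured members was said to stand apart when its median log2 ratio lay at or above percentile 97.5, or at or below 2.5, of 10000 random lists of the same size drawn from the 50 genes on each side of each member in mean CPM (2000 lists in the alternatives). These percentiles describe the 2 libraries and are not tests of age. The listed genes Ifi30, Mx2, Clec7a, Cxcl11, Ccl19, Aldoa and Ca9 were not analysed here.

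Tested on simulated counts drawn for the 31054 features from the mean profile of the adult library, a class of 5000 cells per library returned 100% of 67 genes changed 2-fold and 49.3% of 67 genes changed 1.5-fold at the 1.5-fold limit, called 0 of 2122 unchanged genes, and its intervals covered the true ratio for 95.1% of genes. A class of 100 cells per library returned 97.0% and 43.3% and called 52 of 2263 unchanged genes. Among 200 unchanged lists, 10 and 5 stood apart. The counts were independent Poisson draws at the median depth of each library, without differences between cells. These rates therefore hold for counting error only. UMIs gathered in few cells, genes that vary together and the lower depth of neutrophil-like cells were not simulated.

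Alternatives planned before the data were examined were a minimum of 500 genes, at most 5% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2, cell cycle genes left out of the variable genes, median-ratio scaling, minimum levels of 10 and 200 CPM, a pseudocount of 1 CPM, the mean over cells of each cell's CPM, cells thinned to 1000 UMIs (shallower cells left out: 22 young and 12 adult monocyte/macrophage-like, 59 and 12 mCherry-rich, 17 and 36 neutrophil-like, 3 and 6 T cell-like cells), no minimum level for list members, and classes weighted alike. Added after the data were seen were the doublet-score filter, the mean of ratios within clusters, cluster 14 alone for T cells, T cell-like cells without those in the NK cell-like cluster of resolution 2, T cell-like and mCherry-rich cells with few macrophage UMIs, and subtraction of free RNA. For the last, a library's monocyte/macrophage-like profile was scaled to the UMIs of 7 macrophage genes in the other classes, among them C1qa, C1qb, C1qc, Apoe, Trem2 and Ms4a7. Counts that would fall below 0 were set to 0. Some genes are not reported here by name. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9, and figures matplotlib 3.10.9.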

Results

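Single-cell RNA expression was measured in cells sorted for mCherry, a red fluorescent protein, from tumours of mice aged 4 weeks (young) and 24 weeks (adult), both labelled d7. Tumours were pooled before the sort, and each age is 1 library made with the 10x Genomics 3' v2 kit, a droplet method that marks each captured polyadenylated RNA with a unique molecular identifier (UMI), with a target of 10000 cells. The title of the study sets the comparison in the question of how young hosts present tumour antigen that antigen-presenting cells have taken up to CD8 T cells. The labels used here name neither the tumour nor the cells that carried the mCherry gene. The young library held 7558 barcodes and 84862471 UMIs, and the adult library held 6279 barcodes and 70988070 UMIs. After filtering, 7089 young cells with medians of 9842 UMIs and 2496 genes and 5773 adult cells with medians of 9659 UMIs and 2382 genes were kept. With 1 library per age there is no replicate and no test. Differences are described by size, every 95% interval covers counting error only, and age cannot be told apart from pool, sort, library, sequencing run and the source of the mice. The strain and vendor of the mice are not given in the sources used here. Positions are for mm10, and levels are UMIs per 1000000 (CPM) of the summed UMIs of a cell class.

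Monocyte/macrophage-like cells made up most of both libraries, and T cell-like and neutrophil-like cells held smaller shares of the young library. T cell-like cells were 1.07% of young cells (exact binomial interval 0.846 to 1.34) and 2.62% of adult cells (2.22 to 3.06), a ratio of 0.41 (0.312 to 0.539). By cluster, the share ratio was 0.553 (0.412 to 0.741) for cluster 14 and 0.0388 (0.0094 to 0.160) for cluster 17, with 2 young and 42 adult cells. T cell-like cells with a UMI of Cd8a, a CD8 T cell gene, numbered 35 young and 24 adult. The class ratio therefore does not stand for CD8 T cells. Neutrophil-like cells were 2.62% (2.26 to 3.02) against 4.88% (4.34 to 5.47), a ratio of 0.537 (0.448 to 0.644). The mCherry-rich cells, which carried 104 mCherry UMIs per cell in the young library and 111 in the adult one, were 7.69% (7.08 to 8.33) against 9.08% (8.35 to 9.85). Mature dendritic cell-like cells, with the migration receptor gene Ccr7 among their markers, numbered 39 and 43, and the interval of their share ratio, 0.48 to 1.14, spanned 1. Cluster 6, with 600 young and 461 adult cells, was led by Klrb1b, Il1r2 and MHC class II genes and had 0 own markers among its 10 leading genes. The naming rule placed it in the monocyte/macrophage-like class, so antigen-presenting cells of other types may be counted there. Monocyte/macrophage-like cells were 81.7% (80.8 to 82.6) of young and 75.8% (74.6 to 76.9) of adult cells, a ratio of 1.08. That ratio moved to 1.41 with coarser clusters, where a cluster of 1262 young and 1892 adult cells stayed unnamed. With unnamed clusters 8 and 13, which held 6.36% of young and 6.76% of adult cells, the class came to 88.1% against 82.5%. All shares are of mCherry-sorted cells, so the gate can set them, and the limit of 5 median UMIs that defined the mCherry-rich clusters was chosen after the data were seen. Adult T cell-like cells were also shallower, with a median of 4403 UMIs against 8568.

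**Figure D1:**
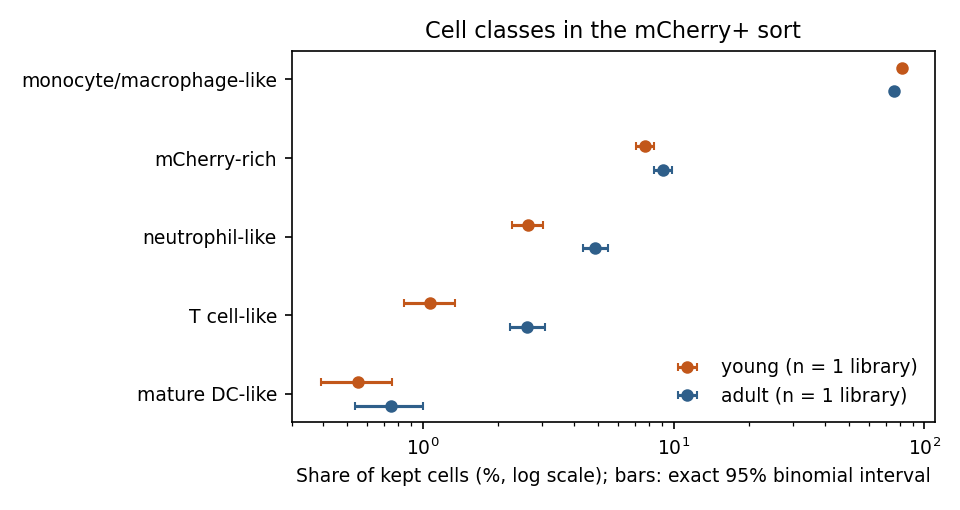
Share of kept cells in each class, in percent on a log axis, for the young (orange) and adult (blue) library; points are 1 library each and bars are exact 95% binomial intervals. T cell-like and neutrophil-like cells were lower in the young library (1.07% against 2.62% and 2.62% against 4.88%), and monocyte/macrophage-like cells were 81.7% against 75.8%.

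In monocyte/macrophage-like cells the largest differences were in genes lower in the young library, led by Ccl24, Mgl2 and Ccl17. Ccl24, a chemokine that attracts eosinophils (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049), stood at 48.7 CPM in young and 1107 CPM in adult cells, 22.7-fold lower (21.9 to 23.6). Ccl17, a ligand of the chemokine receptor CCR4, was at 3.46 against 69.7 CPM, 20.2-fold lower (17.6 to 23.3). Mgl2, a galactose-binding lectin, was at 2.29 against 55.8 CPM, 24.3-fold lower (20.6 to 29.0). Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874735), was 5.73-fold lower (5.47 to 6.0). The chitinase-like protein gene Chil3 was at 126 against 383 CPM, Fn1 (fibronectin) at 322 against 921, Spp1 (osteopontin) at 395 against 1012, S100a4, a calcium-binding protein, at 498 against 1209, Wfdc17 at 258 against 561, and Gatm, the first enzyme of creatine synthesis, at 186 against 385. Genes higher in the young library included Mid1, a microtubule-associated ubiquitin ligase (ENSMUSG00000035299, chromosome X, 169685199 to 170005736), at 86.3 against 18.2 CPM, 4.73-fold (4.40 to 5.09). The selenoprotein gene Selenom was at 279 against 87.9 CPM, 3.17-fold (3.06 to 3.28). Hmox1, which breaks down heme (chromosome 8, 75093621 to 75100589), was at 690 against 305 CPM, 2.27-fold (2.22 to 2.31). The lipid-handling genes Fabp5 (fatty acid binding) and Plin2 (lipid droplet coat) stood at 686 against 261 and 663 against 314 CPM. The list was completed by Rcbtb2 at 91.5 against 35.5 CPM, St3gal5 (ganglioside synthesis) at 51.8 against 19.3, Cacna1d (a calcium channel subunit) at 50.2 against 20.9, Ckb (creatine kinase) at 171 against 79.6, and AC110211.1 at 55.1 against 20.3. The annotation places AC110211.1 antisense to another gene, so its counts are uncertain. Among 2456 genes at 50 CPM or more, 15 were at least 2-fold higher and 11 at least 2-fold lower in young cells.

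The class was not made of the same clusters in both libraries. Clusters 1 and 3 held 31.1% and 29.5% of its adult cells but 8.03% and 4.49% of its young cells, while clusters 2, 4, 5 and 10 held 23.5%, 15.6%, 14.7% and 9.15% of its young cells against 8.18%, 6.52%, 4.82% and 1.10% of its adult cells. The libraries were clustered without integration, and named genes were themselves among the leading genes of clusters. Examples are Ccl24, Timp1, Chil3 and Wfdc17 in cluster 1, Ccl24, Mgl2, Fn1, Spp1 and Gatm in cluster 3, and Hmox1 and Fabp5 in cluster 4. The cluster shares are therefore not independent of these differences, and smaller ratios within clusters can follow from the clustering itself. Within each of the 7 clusters with at least 50 cells of both libraries, Ccl24 stayed lower in the young library (log2 ratio -6.24 to -2.12) and so did Timp1 (-3.14 to -0.98) and Fn1 (-1.78 to -0.48). Mgl2 (-3.42 to -1.36) and Ccl17 (-3.67 to -0.35) did too, but Ccl17 fell short of a 2-fold difference in clusters 2, 4, 5 and 7 (-0.35, -0.53, -0.85 and -0.59), and its log2 ratio of -3.14 over the class had a mean of -1.71 within clusters. Mid1 stayed higher in all 7 (1.5 to 2.29). It spans the pseudoautosomal boundary, where mouse strains differ, so a difference of strain or vendor between the ages cannot be told apart from age for this gene. Of the named genes, 8 fell short of a 2-fold difference in their mean log2 ratio within clusters: Fabp5 (0.41, and below 0 in clusters 3 and 7), Hmox1 (0.67), Plin2 (0.68), Ckb (0.83), AC110211.1 (0.89), Cacna1d (0.93), Wfdc17 (-0.80) and Gatm (-0.83).

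Interferon-stimulated genes as a group were higher in young monocyte/macrophage-like cells. Of 21 measured type I interferon response genes, 9 were higher by at least 1.5-fold and 0 were lower, with a median log2 ratio of 0.48 at the 100th percentile of matched random lists. Cluster 5, led by Ifit3, Ifit2, Cmpk2 and Ifit1, held 14.7% of the young and 4.82% of the adult cells of the class, and within clusters the median was 0.35, still apart from random lists. Among the members the antiviral gene Oasl1 was at 172 against 86.6 CPM, the interferon regulator Irf7 at 937 against 492, Ifit3 at 111 against 58.3 and Rsad2 (viperin) at 328 against 178. Of 16 interferon gamma response genes, 3 were higher (the GTPases Irgm1, Gbp4 and Igtp) and 1 was lower (Serpina3g), with a median of 0.29. Iron and heme handling genes had the largest positive median, 0.75 over 6 measured members, of which 4 were higher and 0 lower. Besides Hmox1 these were Blvrb (biliverdin reductase, 518 against 278 CPM), Slc11a1 (a phagosomal metal transporter, 286 against 159) and Ftl1 (ferritin light chain, 21775 against 13648). Of 11 lipid-associated macrophage genes 4 were higher (Fabp5, Plin2, the lysosomal lipase Lipa and the cholesterol exporter Abca1) and 1 was lower (Spp1), with a median of 0.46. Lysosome and cathepsin genes had a median of 0.24 over 18 members, 1 of them past 1.5-fold (Ctsl, cathepsin L, 577 against 341 CPM).

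Cholesterol synthesis genes were lower in young monocyte/macrophage-like cells, with 8 of 12 measured members lower, 0 higher and a median log2 ratio of -0.57. Fdps, which makes farnesyl diphosphate, was at 15.5 against 46.1 CPM (2.97-fold lower, 2.75 to 3.21) and the sterol demethylase Cyp51 at 5.64 against 18.1 CPM (3.21-fold lower, 2.83 to 3.64). MHC class II genes had a median of -0.54 over 9 members, 2 of which were lower by 1.5-fold, the peptide-exchange gene H2-DMb2 (26.9 against 52.2 CPM) and the class II transactivator Ciita (25.4 against 44.2 CPM). The class II median was -0.14 within clusters, where it no longer stood apart from random lists. Unfolded protein and integrated stress response genes had a median of -0.34 over 14 members, 2 lower and 1 higher (Ddit3). Ribosomal protein genes (-0.36, 20 members) and mitochondrially encoded genes (-0.30, 12 members) were lower as groups, with 1 member past 1.5-fold, mt-Nd3. MHC class I presentation genes did not stand apart: 0 of 16 members were past 1.5-fold in either direction and the median was 0.04. The same held for cross-presentation machinery (0 of 16, 0.10), and for coinhibitory ligands (median 0.03), where 1 of 7 was lower, Pdcd1lg2 (PD-L2) at 48.0 against 81.7 CPM. Alternatively activated and resident macrophage genes had a median of -0.06, with 3 of 12 lower (Ccl24, Chil3 and the mannose receptor Mrc1, 10.0 against 41.4 CPM) and 9 within 1.5-fold. Smaller medians stood apart but lost that standing in at least 1 alternative: inflammatory macrophage genes (0.15, and 0.01 within clusters), oxidative phosphorylation (-0.12, and -0.06 within clusters), angiogenic factors (-0.28 over 4 members, and -0.02 with no minimum level) and cytotoxic T cell genes (0.31 over 4 members, and 0.19 in thinned cells).

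**Figure D2:**
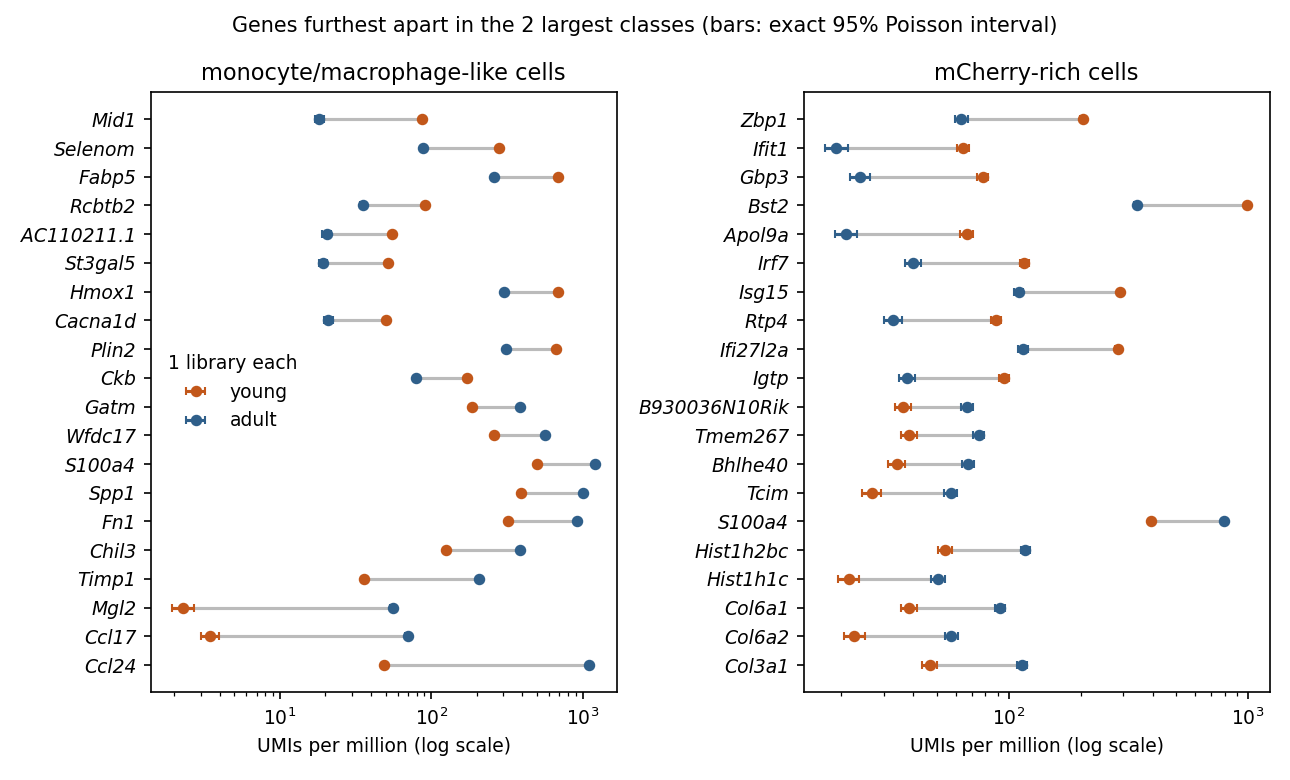
Levels of the 10 genes furthest apart in each direction in monocyte/macrophage-like (left) and mCherry-rich (right) cells, in UMIs per 1000000 (CPM) on log axes. Points are the young (orange) and adult (blue) library, bars are exact 95% Poisson intervals and grey lines join the pair; Ccl24 stood at 48.7 against 1107 and Zbp1 at 205 against 63.5.

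Among the 10 genes furthest apart in each direction in mCherry-rich cells, those higher in the young library were mostly interferon-stimulated and those lower included collagen genes. Zbp1, a sensor of Z-form nucleic acid (ENSMUSG00000027514, chromosome 2, 173206612 to 173218923), was at 205 CPM in young and 63.5 CPM in adult cells, 3.23-fold higher (3.01 to 3.46). Ifit1, which binds viral RNA, was at 64.5 against 19.1 CPM (3.38-fold, 2.99 to 3.84), and the GTPase gene Gbp3 at 78.1 against 24.0 CPM (3.25-fold, 2.91 to 3.64). Bst2 (tetherin, chromosome 8, 71534255 to 71537456), which holds budding virus at the cell surface, was at 992 against 344 CPM (2.88-fold, 2.80 to 2.97), or 31.6 against 11.3 UMIs per cell. Apol9a, Irf7, the ubiquitin-like Isg15 (294 against 110 CPM), Rtp4, Ifi27l2a and the GTPase gene Igtp (95.4 against 37.5 CPM) followed. Of these, Irf7, Isg15, Rtp4 and Ifi27l2a, and Bhlhe40 among the genes below, were within 2 times their lowest level in UMIs per cell in the other classes, close to what free RNA can give. Lower in the young library were the collagen genes Col3a1 (46.7 against 114 CPM, 2.44-fold lower, 2.25 to 2.65), Col6a2 (22.7 against 57.6) and Col6a1 (38.5 against 92.2), the histone genes Hist1h1c and Hist1h2bc, S100a4 (395 against 794), Tcim, Bhlhe40, Tmem267 and B930036N10Rik. Tcim turned to a log2 ratio of 0.25 when each cell weighed the same. Some of these were lower mainly in cluster 11: Hist1h1c had log2 ratios of -0.10 in cluster 9 and -1.31 in cluster 11, Hist1h2bc of -0.33 and -1.24, B930036N10Rik of -0.15 and -0.96, and Tcim of 0.98 and -1.25. Of 2247 genes at 50 CPM or more, 26 were at least 2-fold higher and 7 at least 2-fold lower in young cells.

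All 19 measured type I interferon response genes were higher by at least 1.5-fold in young mCherry-rich cells, with a median log2 ratio of 1.04 at the 100th percentile of matched random lists. Ifit3 was at 47.1 against 8.63 CPM (5.46-fold, 4.58 to 6.55). MHC class I presentation genes were higher too: 12 of 16 passed 1.5-fold, 0 were lower, and the median was 0.65. They included the immunoproteasome subunits Psmb9 (112 against 47.1 CPM, 2.37-fold, 2.18 to 2.57) and Psmb8 (528 against 292), the class I heavy chain H2-K1 (554 against 319), the light chain B2m (2076 against 1288) and the peptide transporter Tap1 (81.2 against 46.5). Of 14 interferon gamma response genes 10 were higher and 1 lower (Serpina3g), with a median of 0.64 and Gbp4 at 68.8 against 29.4 CPM. Coinhibitory genes were higher for 3 of 5 members (median 0.51), namely Cd274 (PD-L1, 61.9 against 41.1 CPM), Vsir and Lgals9, but the list did not stand apart in thinned cells (0.33). Matrix and epithelial to mesenchymal transition genes had a median of -0.17, with Col3a1 and Fn1 (108 against 176 CPM) lower and 10 of 12 within 1.5-fold. The list did not stand apart in thinned cells (-0.09). Cholesterol synthesis genes had a median of -0.29, 2 of 12 lower (Mvd and Insig1). They did not stand apart in thinned cells, where the median did not shrink (-0.31) but far fewer UMIs were left. The p53 targets had a median of 0.19 with 0 of 11 past 1.5-fold. DNA replication (-0.13), immediate early (-0.16) and mitochondrially encoded genes (-0.21) were lower as groups by less than 1.5-fold at the median. The first of them had a thinned median of 0.08, and the immediate early genes one of 0.28 when each cell weighed the same. The mitochondrially encoded genes no longer stood apart in either of these settings (-0.028 thinned and -0.061). RNA of monocyte/macrophage-like cells was estimated at 7.27% of the UMIs of young and 6.12% of adult mCherry-rich cells. Of the macrophage-type lists in this class, lysosome genes (0.28) and inflammatory genes (0.35) still stood apart once that RNA was subtracted, at 0.15 and 0.24, and the lysosome genes did not in thinned cells (0.20). Cross-presentation machinery had a median of 0.16, with 2 of 13 members higher, among them the phagocyte gene Cyba, and of -0.06 once that RNA was subtracted.

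**Figure D3:**
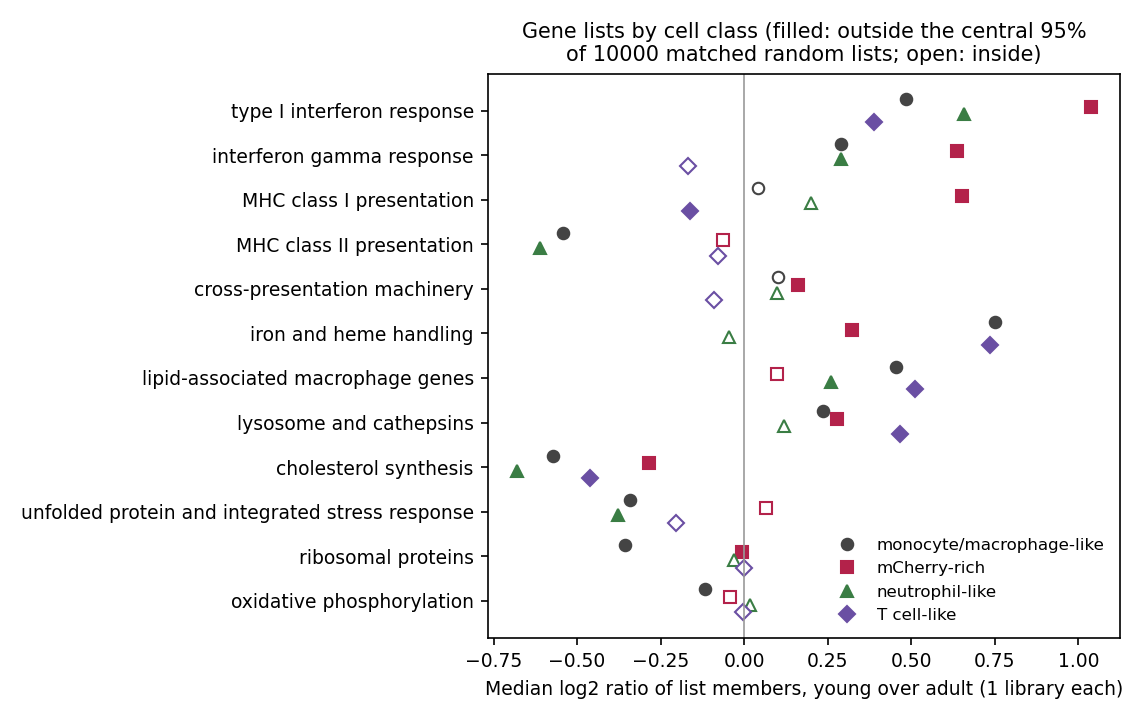
Median log2 ratio (young over adult, 1 library each) of the measured members of 12 gene lists in 4 cell classes. Filled symbols lie outside the central 95% of 10000 random lists matched on level and open symbols inside; type I interferon response genes were to the right of 0 in the 4 classes (0.48, 1.04, 0.66 and 0.39) and cholesterol synthesis genes to the left (-0.57, -0.29, -0.68 and -0.46).

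Neutrophil-like cells, with 186 young and 282 adult cells, had higher interferon-stimulated genes and lower immediate early and dissociation genes in the young library. Ifit2, an interferon-induced RNA-binding protein, was at 144 against 40.4 CPM (3.57-fold, 2.39 to 5.45), and Inhba, a subunit of activin, at 815 against 271 CPM (3.01-fold, 2.57 to 3.53). Stfa2, a cysteine protease inhibitor, had 42 UMIs in 8 young cells against 2 in 2 adult cells, Gm12589 48 against 16, and Mid1 51 against 11. Mid1 had a log2 ratio of 2.19 here, but of 0.41 without the highest doublet scores, and Mid1 and Ifit2 were both near their lowest level in the other classes. Lower were Ccl24 (3 against 514 UMIs, 134-fold lower, 45.6 to 653), the acute phase gene Saa3 (7 UMIs in 3 young cells against 94 in 4 adult cells), the heat shock gene Hspa1b (6 UMIs in 4 cells against 69 in 18), Wfdc17 (533 against 2124 CPM, 3.99-fold lower, 3.55 to 4.48) and Hist1h1c. Of the adult Ccl24 UMIs, carried by 34 cells, 246 were in 1 cell, and the log2 ratio of -6.01 was -2.21 without the highest doublet scores. Subtraction of macrophage RNA left 0 young and 156 adult Ccl24 UMIs, which gives no size. Of 20 type I interferon response genes 12 were higher and 0 lower, with a median of 0.66 and Ifit3 at 516 against 174 CPM. Interferon gamma response genes had a median of 0.29 with 5 of 17 higher, among them the chemokine Cxcl10 (1410 against 794 CPM), but did not stand apart in thinned cells (0.11). Of 18 immediate early and dissociation genes 5 were lower (median -0.47), among them Klf2 at 270 against 883 CPM and Hspa1a at 92.6 against 358. Unfolded protein response genes had 6 of 17 lower (-0.38; Dnajb9 at 98.7 against 259 CPM) and glycolysis and hypoxia genes 4 of 20 (-0.25; Ero1l at 273 against 549 CPM). Cholesterol synthesis genes had a median of -0.68 with 2 of 10 lower, but did not stand apart in thinned cells (-0.51). MHC class II genes had a median of -0.61 with 4 of 9 lower, but of -0.30, no longer apart from random lists, once macrophage RNA was subtracted. That RNA was estimated at 35.0% of the UMIs of young and 38.4% of adult neutrophil-like cells, whose median depth was 2218 and 1971 UMIs. Of 2311 genes compared, 50 were at least 2-fold higher and 29 at least 2-fold lower.

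T cell-like cells, with 76 young and 151 adult cells, had higher Ccl3, Ccl4 and some cytotoxic genes in the young library. Ccl4, a chemokine (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683), was at 3708 against 755 CPM (4.91-fold, 4.54 to 5.31) and its neighbour Ccl3 at 1467 against 346 CPM (4.24-fold, 3.76 to 4.78). With cells rich in macrophage UMIs left out, Ccl4 was at 4538 against 602 CPM and Ccl3 at 1646 against 330 CPM. The limit was the 95th percentile of macrophage UMIs in each library's neutrophil-like cells. It was looser in the young library (43.25 UMIs) than in the adult one (27.95 UMIs). Of 14 cytotoxic and exhausted T cell genes 7 were higher, 0 were lower and the median was 0.42. Gzma, the granzyme A gene, was at 1890 against 707 CPM (2.67-fold, 2.45 to 2.92), the inhibitory receptor Lag3 at 334 against 136 (2.46-fold, 2.0 to 3.03), Ifng (interferon gamma) at 515 against 257, Prf1 (perforin) at 274 against 148 and Pdcd1 (PD-1) at 108 against 69.4. Gzmb, a further granzyme gene, was at 2131 against 2091 CPM, a ratio of 1.02 (0.957 to 1.09). S100a8 (53 UMIs in 7 young cells against 8 in 8 adult cells), Mmp13 (45 UMIs in 7 cells, 32 of them in 1 cell, against 7 in 3) and Tnfaip2, the last near its lowest level in the other classes, were higher as well. Lower were Ccl24 (1 against 110 UMIs, 86.4-fold lower, 15.2 to 3443), Ccl17 (1 UMI against 107 in 4 adult cells, 99 of them in 1 cell), Tmem176a (4 against 149 UMIs), Tmem176b (7 against 175 UMIs) and Ly6g5b (0 against 62 UMIs, at least 16.2-fold lower against 3 counts). In cluster 14 alone Tmem176a, Tmem176b and Ly6g5b had log2 ratios of -1.84, -1.89 and -1.42, against -3.90, -3.67 and -3.68 in the class. For Ccl24 the macrophage RNA to be subtracted exceeded the UMIs of both libraries, so no ratio remained. Its log2 ratio of -4.14 was -2.78 in cells with few macrophage UMIs and -2.37 without the highest doublet scores, and 69 of the 110 adult UMIs were in 1 cell. Type I interferon response genes had 8 of 20 higher and a median of 0.39 (Oasl1 at 82.3 against 25.7 CPM), which was 0.17 and no longer apart from random lists after that subtraction. Cholesterol synthesis genes had 5 of 13 lower (-0.46, with Cyp51 at 3.63 against 20.9 CPM). They did not stand apart in thinned cells, where the median did not shrink (-0.52) but fewer UMIs were left. Nor did the cholesterol genes stand apart once macrophage RNA was subtracted (median -0.33). MHC class I presentation genes had a median of -0.16 with 0 of 16 past 1.5-fold. The median was -0.36, still apart from random lists, once macrophage RNA was subtracted, and -0.0035, no longer apart, in cluster 14 alone. Macrophage RNA was estimated at 35.2% of the UMIs of young and 32.8% of adult T cell-like cells, so lists of macrophage-type genes in this class stand beside that share. Per cell this RNA came to 35.8% (young) and 21.4% (adult) of the UMIs of a monocyte/macrophage-like cell. In mCherry-rich cells it was 21.6% and 18.7%, and in neutrophil-like cells 11.6% and 10.7%. The amounts were not alike across classes, so RNA of doublets was not told apart from free RNA in this estimate. Of 2656 genes compared, 74 were at least 2-fold higher and 78 at least 2-fold lower.

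The T cell-like class held cluster 14 (74 young and 109 adult cells) and cluster 17 (2 and 42 cells), and T cell genes chosen after their values were seen were compared in both. Trdc, the constant region of the delta T cell receptor chain, was at 150 against 762 CPM in the class but at 122 against 74.3 CPM in cluster 14 (1.64-fold, 1.18 to 2.29), and over all cells Il17a, the interleukin 17 gene, had 29 UMIs in 2 young cells against 333 UMIs in 47 adult cells. In cluster 14, where Cd8a and Cd4 mark the CD8 and CD4 lineages, Cd8a was at 281 against 164 CPM (1.71-fold, 1.38 to 2.13) and Cd4 at 29.3 against 94.7 CPM, a ratio of 0.309 (0.187 to 0.494). Foxp3, the regulatory T cell factor, was at 33.0 against 45.5 CPM, with an interval of 0.425 to 1.22 that spanned 1. Ccl4 was still 3.99-fold (3.69 to 4.32) and Ccl3 3.46-fold (3.08 to 3.91) higher in this cluster, and the median of the cytotoxic list was 0.45. At Leiden resolution 2 a natural killer (NK) cell-like cluster of 19 young and 26 adult cells, all from cluster 14, came apart. Without these cells the T cell-like class, cluster 17 still included, held 57 young and 125 adult cells. Its cytotoxic median was 0.21, still apart from random lists, and Gzma was at 256 against 290 CPM, a ratio of 0.885 (0.72 to 1.08). Ccl4 (6.07-fold, 5.55 to 6.65), Ccl3 (4.43-fold, 3.92 to 5.02), Prf1 (4.48-fold, 3.09 to 6.63), Lag3 (2.70-fold, 2.17 to 3.38) and Ifng (2.13-fold, 1.80 to 2.51) stayed higher, and the interval of Pdcd1, 0.986 to 1.93, spanned 1. Cluster 17, mostly adult, had 0 UMIs of Lag3 and Ifng, so these ratios also reflect the makeup of the class. Cluster 14 without its NK cell-like cells was not compared by itself.

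Over all kept cells, type I interferon response genes were higher in the young library for 15 of 21 members (median log2 ratio 0.61; Irf7 at 748 against 370 CPM) and cholesterol synthesis genes lower for 7 of 12 (-0.53; Fdps at 25.3 against 53 CPM). Iron and heme handling genes had 4 of 7 higher (0.65), and MHC class II genes 2 of 9 lower (-0.42). Matrix genes had 4 of 10 lower (-0.33; Timp1 at 41.1 against 164 CPM and Col1a1, a fibroblast collagen, at 0.238 against 12.7 CPM), but with the classes weighted alike in both libraries the median was -0.06 and no longer apart from random lists. MHC class I genes had a median of 0.15, and of 0.10 under that weighting, which ended the call. Of 2466 genes compared, 18 were at least 2-fold higher and 10 at least 2-fold lower, and the weighting left 10 higher.

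The sex-linked genes gave the same picture in both libraries. Xist, the RNA that silences the second X chromosome of females, was found in 94.1% of monocyte/macrophage-like cells of each library, with median depths of 10096 and 9814 UMIs. In mCherry-rich cells it was found in 27.3% of young (23.6 to 31.3) and 25.6% of adult cells (21.9 to 29.5), although these were deeper, with medians of 22714 and 28754 UMIs. The Y-linked genes Ddx3y and Eif2s3y had 0 UMIs in both libraries, which allows a share of up to 0.0423% of young and 0.052% of adult cells with a UMI. Uty had 1 UMI in each library, and Kdm5d had 2 in the young and 0 in the adult one.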

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

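The 2 tests of where mCherry UMIs outside the mCherry-rich clusters come from were chosen after the result was seen. Several gene groups lay on opposite sides of 0 in different cell classes of the same 2 libraries, and none of these differences between classes was tested. MHC class I presentation genes, which load peptide for CD8 T cells, had a median log2 ratio of 0.65 in mCherry-rich cells and of -0.16 in T cell-like cells, 0.82 apart. The T cell-like value was -0.36, still apart from random lists, with free RNA subtracted, and -0.0035, no longer apart, in cluster 14 alone. Alternatively activated and resident macrophage genes had a median of 0.21 in mCherry-rich cells and of -0.34 in T cell-like cells, 0.56 apart. The first of these medians had a mean of the opposite sign (-0.36, with Ccl24 and Chil3 lower and 5 of 7 members within 1.5-fold), and the second changed its sign in several alternatives. Monocyte and neutrophil attracting chemokines had a median of 0.41 in mCherry-rich cells (Ccl7 and Csf1 higher) and of -0.31 in neutrophil-like cells (Ccl8 and Csf1 lower, Cxcl1 higher), 0.72 apart. In T cell-like cells the median of this list was 0.32, which is 0.63 from the neutrophil-like value. The neutrophil-like list no longer stood apart with free RNA subtracted (-0.39), in thinned cells (-0.19) or without the highest doublet scores (-0.0032), and the T cell-like list did not in thinned cells (0.18) or in cluster 14 alone (0.21). A cluster of 9 fibroblast-like cells, led by Col1a1, Col1a2 and Igfbp7, was 0.156% of adult cells and entered no comparison. In the young library 0 such cells were found, which allows a share of up to 0.0423%.

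mCherry UMIs were also found in cells outside the mCherry-rich clusters, namely in 17.3% of young (exact binomial interval 16.3 to 18.3) and 17% of adult (15.9 to 18.1) monocyte/macrophage-like cells, and the cells with such UMIs were not compared between the ages. Without the highest cell of each class, monocyte/macrophage-like cells had 1.75 times the mCherry UMIs per cell of T cell-like cells in the young library. The adult ratio was 1.11. These ratios cannot decide on uptake by phagocytes as the main source. The T cell-like cells were sorted for mCherry too, and the young ones held only 11 such UMIs in 76 cells. Adult T cell-like cells were also shallower than monocyte/macrophage-like cells (median 4403 against 9814 UMIs). Free RNA shared by all droplets is consistent with the shares, since the larger of the 2 libraries' differences between monocyte/macrophage-like and T cell-like cells (14.5% of young, 15.9% of adult) was 2.79 percentage points and the intervals overlapped. In cells thinned to 1000 UMIs the shares were 2.27% and 2.38% in monocyte/macrophage-like cells and 8.28% and 5.28% in neutrophil-like cells. In T cell-like cells they were 1.37% (1 of 73 cells) and 4.83% (7 of 145). Before thinning, neutrophil-like cells stood at 17.2% of young and 12.1% of adult cells, with median depths of 2218 and 1971 UMIs. Thinning removes a larger part of the UMIs of deeper cells, so the thinned shares do not compare mCherry UMIs per cell between classes. Uptake by phagocytes stays open, also in the 11 young and 8 adult monocyte/macrophage-like cells with at least 5 mCherry UMIs. Doublets with mCherry-rich cells stay open there too. The highest monocyte/macrophage-like cell held 67 mCherry UMIs in the young and 87 in the adult library, against medians of 65 and 84 in mCherry-rich cells. The highest adult T cell-like cell also held 87. Uptake of protein without its RNA, and age, were not tested and stay open as well.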

How the results depend on the processing

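The doublet-score filter, the means within clusters, cluster 14 alone, T cell-like cells without NK cell-like cells, cells with few macrophage UMIs and the subtraction of free RNA were added after the data were seen, and the other alternatives were planned. Over both kinds, single-gene log2 ratios kept their direction and size class in 539 comparisons with an alternative, fell below the limit in 10 and changed sign in 1. List medians kept their standing in 535, lost it in 65 and changed sign in 18. Share ratios stayed within their interval in 28 and left it in 5, and counts of genes stayed within 1.5 times the main count in 23 (higher) and 27 (lower) and left that range in 18 and 14. Some settings could change little, so these counts do not measure robustness. Keeping doublets returned only 1 cell per library, and median-ratio scaling shifted log2 ratios by -0.086 (neutrophil-like) to 0.038 (T cell-like). T cell-like and neutrophil-like cells held 76 and 186 young cells, so few cells limit their values. No paired analysis was possible because each age is 1 library, so the groups share replicate number 1 only. The share ratio of mature dendritic cell-like cells had no value with cell cycle genes left out or with the doublet-score filter, and neither did the alternatively activated list in mCherry-rich cells and the monocyte and neutrophil attracting chemokines in T cell-like cells with free RNA subtracted. Except where the number of genes compared explains a count or unnamed clusters move a share ratio, the cause was not tested.

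The share ratio of monocyte/macrophage-like cells (1.08) was 1.23 with a minimum of 500 genes, 1.29 with at most 5% mitochondrial UMIs, 1.03 with doublets kept, 1.41 at Leiden resolution 0.5 and 1.18 at resolution 2. In each of these settings the naming rule kept other clusters nearest the macrophage list out of the class. With a minimum of 500 genes these held 891 young and 559 adult, 306 and 970, and 455 and 207 cells. With at most 5% mitochondrial UMIs they held 491 and 1179, 477 and 183, and 161 and 102 cells. A minimum of 10 CPM, which compares more genes, gave 41 higher and 46 lower genes in monocyte/macrophage-like, 66 and 17 in mCherry-rich, 259 and 114 in neutrophil-like and 215 and 343 in T cell-like cells. A minimum of 200 CPM, which compares fewer, gave 6 higher genes in monocyte/macrophage-like cells, 6 higher and 1 lower in mCherry-rich, 12 and 11 in neutrophil-like and 28 and 14 in T cell-like cells. Thinned to 1000 UMIs per cell, mCherry-rich cells had 83 higher and 25 lower genes, neutrophil-like cells 110 and 56, and T cell-like cells 135 higher. The mean over cells of each cell's CPM gave 43 higher genes in mCherry-rich and 119 lower genes in T cell-like cells. Subtraction of free RNA (added) gave 311 higher and 89 lower genes in neutrophil-like and 112 and 188 in T cell-like cells, and the doublet-score filter (added) 113 and 63, and 197 and 127. Where the subtraction exceeded the UMIs of a gene the count was set to 0, which sets some of these ratios. Without NK cell-like cells (added) 121 genes were higher in T cell-like cells. With classes weighted alike, 10 genes were higher over all cells and mitosis genes moved from -0.15 to 0.044.

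Thinning moved list medians in mCherry-rich cells to 0.081 (DNA replication, from -0.13), 0.52 (alternatively activated), -0.31 (cholesterol), 0.33 (coinhibitory), 0.15 (cross-presentation), -0.088 (matrix), -0.029 (immediate early), 0.28 (iron and heme), 0.20 (lysosome), -0.028 (mitochondrially encoded) and -0.042 (ribosomal protein). In monocyte/macrophage-like cells it gave 0.19 (cytotoxic), 0.042 (inflammatory) and -0.10 (oxidative phosphorylation), and in T cell-like cells 0.11 for alternatively activated genes (from -0.34). With the mean over cells of each cell's CPM, Tcim in mCherry-rich cells turned to 0.25, and medians there were -0.0014 (DNA replication), 0.28 (coinhibitory), 0.28 (immediate early, from -0.16), -0.061 (mitochondrially encoded) and -0.070 (ribosomal protein). The same setting gave 0.26 (cytotoxic) and 0.10 (inflammatory) in monocyte/macrophage-like cells and 0.19 for alternatively activated genes in T cell-like cells. With no minimum for list members the medians in mCherry-rich cells were 0.016 (alternatively activated), 0.084 (coinhibitory) and 0.088 (cross-presentation), those in monocyte/macrophage-like cells -0.018 (angiogenic) and 0.014 (cytotoxic), and that of costimulatory genes in T cell-like cells -0.045 (from 0.42). A minimum of 500 genes gave 0.10 (inflammatory) and -0.093 (oxidative phosphorylation) in monocyte/macrophage-like cells.

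Among the added alternatives, the doublet-score filter moved alternatively activated genes in T cell-like cells to 1.89 and costimulatory genes there to -0.049. It gave -0.19 (angiogenic), 0.13 (inflammatory) and -0.11 (oxidative phosphorylation) in monocyte/macrophage-like cells, and ribosomal protein genes in mCherry-rich cells turned from -0.0067 to 0.0057. In cells with few macrophage UMIs these 2 T cell-like lists stood at 0.35 and -0.087 and the ribosomal list at 0.0095, and in cluster 14 alone the alternatively activated list stood at 0.36. Subtraction of free RNA gave -0.29 for costimulatory genes in T cell-like cells, and -0.064 (cross-presentation), 0.015 (ribosomal protein) and 0.15 (phagocytic receptors, from 0.37) in mCherry-rich cells. Means within clusters were -0.14 (MHC class II), 0.010 (inflammatory) and -0.063 (oxidative phosphorylation) in monocyte/macrophage-like cells, and 0.059 (immediate early) and 0.018 (ribosomal protein) in mCherry-rich cells.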

Other observations

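In this part the tests of a library-wide shift (Timp1, Fn1, Gatm and S100a4) and the 3 tests of genes induced by interleukin 4 were chosen after the result was seen. In T cell-like cells, T cell attracting chemokines had 5 of 8 measured members higher and 2 lower in the young library. Besides Ccl3 and Ccl4, the ligands Cxcl9 (234 against 82.8 CPM), Cxcl16 (413 against 225) and Ccl5 (3082 against 1729) were higher, and Ccl17 and Ccl22 (1.21 against 57.1 CPM), both ligands of CCR4, were lower, but 4 adult cells carried all 107 Ccl17 UMIs and 4 all 60 Ccl22 UMIs of the adult class, 99 and 41 of them in 1 cell. The median log2 ratio of the list was 0.85 and its mean -0.0049, of the opposite sign. In mCherry-rich cells, where Cxcl10 and Ccl4 were higher and Ccl17 lower, the median was 0.32 and the mean -0.044, again of the opposite sign. In T cell-like cells, phagocytic receptor genes had 6 of 13 higher and 0 lower (median 0.71, Fcgr4 at 342 against 136 CPM) and matrix genes 5 of 7 lower (-0.60, Vim at 1664 against 2525 CPM). Both stand beside the 35.2% and 32.8% of UMIs that macrophage RNA was estimated to hold there. In the same T cell-like cells, immediate early genes had 6 of 18 lower, with Klf2, a factor of resting T cells, at 46.0 against 192 CPM, but their median of -0.16 did not stand apart.

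In monocyte/macrophage-like cells the phagocytic receptor genes Fcgr4 (an activating antibody receptor, 920 against 591 CPM), Cd36 (a scavenger receptor, 66.9 against 39.1) and Mertk (which binds dying cells, 13.4 against 5.94) were higher and Mrc1 was lower, with a list median of 0.14 that did not stand apart. Transforming growth factor beta genes did not stand apart (median -0.032), with 2 of 11 lower (Tgfb1 at 301 against 457 CPM and Id1 at 54.3 against 84.6), 1 higher (Tgfb3 at 13.3 against 5.0) and 8 within 1.5-fold. In neutrophil-like cells 4 of 11 lipid-associated genes were higher (median 0.26, Abca1 at 85.0 against 33.3 CPM), among them Spp1 at 3832 against 1930 CPM, which was lower in young monocyte/macrophage-like cells. That neutrophil-like list lost its standing without the highest doublet scores, in thinned cells and with a pseudocount of 1 CPM.

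The 10 named genes lower in young monocyte/macrophage-like cells (Ccl24, Mgl2, Ccl17, Timp1 and others) were weighed against technical explanations. Within clusters the median of the 10 genes was -1.23. Free RNA was not subtracted in this class, so RNA of clusters 1 and 3, which held mostly adult cells, may lie in the others. The value therefore cannot exclude different shares of the clusters as the cause. In clusters 1 and 3 themselves Ccl24 was lower too (log2 ratio -3.76 and -3.24). Depth per cell is argued against as the whole cause, since the median was -1.62 in cells thinned to 1000 UMIs and median depths were close (10096 and 9814 UMIs). For Timp1, Fn1 and Gatm a library-wide shift is argued against by a median gap of -1.33 to the ratios of mCherry-rich cells with free RNA subtracted, while for S100a4, lower in the 4 classes compared (log2 ratio -1.27, -1.0, -0.92 and -1.34), the gap was -0.29 and such a shift stays open. The other 6 genes were too low in mCherry-rich cells for this test, and the split between S100a4 and the other 3 genes was made after their joint value was seen. Age, pool, run and the source of the mice cannot be told apart.

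A hypothesis for Ccl24, Ccl17, Mgl2, Mrc1 and Chil3 is that the young library may hold a weaker response to interleukin 4 type signals, although the list of alternatively activated and resident macrophage genes, fixed before the data were examined, did not stand apart (median -0.063, 9 of 12 within 1.5-fold). Of 14 other genes known to be induced by interleukin 4 in macrophages, 8 were measured, 5 of them were lower and 0 higher, and the median log2 ratio was -0.71, at percentile 0.0 of 10000 matched random lists. Cdh1 (6.75 against 44.9 CPM) and Matk (9.04 against 39.4) had been seen among the leading genes of cluster 3, which held mostly adult cells. Without them 3 of 6 measured genes were lower, among them Egr2 (18.2 against 38.3 CPM), and the median was -0.52 at percentile 0.0. Within clusters it was -0.40, also at percentile 0.0. Free RNA was not subtracted in this class, so that value cannot exclude cluster shares as the cause. The interleukin genes were too sparse to compare, with Il4 at 4 UMIs against 0 and Il13 at 91 UMIs in 4 young cells against 138 UMIs in 8 adult cells.

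Type I interferon response genes, higher in young mCherry-rich cells, kept a median log2 ratio of 1.20 with free RNA of monocyte/macrophage-like cells subtracted, of 0.97 within clusters 9 and 11, and of 1.18 without the highest doublet scores. The first 2 values argue against free RNA and cluster shares as the whole cause. Doublets stay open, because the doublet caller has not worked on these libraries and its scores need not mark them. The list was higher in monocyte/macrophage-like cells as well (0.48), so a shift of the whole library stays open, as does a difference between the tumours of young and adult hosts, which was not tested.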
